A study of Rattus norvegicus with 5 samples.

How the data were processed

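RNA abundance was measured in rat vascular smooth muscle cells, the contractile cells of the blood vessel wall, in 5 libraries, 1 for each of 5 conditions: an untreated control, hypoxia for 24 h, and hypoxia for 24 h after pretreatment with DPN (0.1 µM), In-Cl (0.1 µM) or E2 (10 nM). All 3 compounds act on estrogen receptors. E2 is estradiol, the natural steroid hormone, DPN is a diarylpropionitrile that prefers estrogen receptor beta, and In-Cl is named in the series title as an indazole compound. Total RNA was extracted with Trizol and made into libraries with a stranded SMARTer kit, per the labels' protocols. There are no replicates, so no difference has a replicate check, no p-value is given, and every statement compares libraries, not conditions.

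The authors deposited 1 table per library with a log2 expression value for each of 17048 rows, and the rows carry a gene symbol and stand in the same order in all 5 tables. TopHat, edgeR and build rn6 are named, per the submitters' processing notes; the counting program, the annotation, the use of strand in counting and all versions are not given in the sources used here. The deposited log2 values equal log2 of a linear value plus 1, and the linear values look like read counts adjusted to a common library size: the low linear values of a library come in equal steps. A step was found for each library from the rows up to 2.5 reads, and 88.1% of these low values in the control, 99.2% in the E2 library and 100% in the other 3 lay within 0.2 read of a whole number of steps. The step is worth 0.848 in the control, 1.03 in hypoxia, 0.986 with In-Cl, 1.06 with DPN and 1.10 with E2, and dividing by it gives approximate reads. The linear values sum to between 20663687 (control) and 22837695 (hypoxia) per library, which corresponds to about 20200000 reads with E2, the fewest, and 24400000 in the control, the most. The tests had been planned for read counts; because the tables hold log2 values, no count model was fitted, and the alternatives set in advance that need counts (other size factors and CPM) were not run.

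The main quantity is the difference of deposited log2 values between 2 libraries. A row was called detected when any library had a deposited value above 0 (13397 rows). Counts of genes were made over the 6699 rows with the highest mean linear value over the 5 libraries (upper 50% of detected rows, mean of at least 310.5). A gene was counted as higher or lower at a 2-fold difference. For single genes a 95% interval of the log2 difference was computed from the approximate reads of the 2 libraries (exact Clopper-Pearson interval of the share of reads). These intervals and the exact Poisson intervals of single levels cover counting error only, not the variation between cultures, and reads without molecular identifiers are not independent molecules. A fold against a library listed at 0 was computed against a floor of 3 reads. In an alternative, values under 3 reads were raised to that level, which differs by library (linear 2.54 in the control, 3.10 in hypoxia, 3.29 with E2). A gene under it in both libraries then takes a fixed difference, 0.21 for hypoxia against control and 0.07 for E2 against hypoxia.

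The 28 gene lists were fixed before the data were examined: glycolysis, hypoxia response, prostanoid synthesis and receptors, inflammation, interferon, estrogen receptors, estrogen targets, contractile genes, synthetic smooth muscle phenotype, extracellular matrix, cell cycle, mitochondrial respiration, cholesterol synthesis, endoplasmic reticulum stress and amino acid response, oxidative stress, immediate early genes, heat shock, markers of endothelial cells, leukocytes, fibroblasts, adipocytes, neural crest or glia, epithelium and erythroid cells, ribosomal protein genes, histones, mitochondrially encoded genes and small noncoding RNAs. The last 2 were not tested, since 0 mitochondrially encoded and 2 small noncoding members were detected. A list was placed by the percentile of its median log2 difference among 10000 random lists of the same size, matched on mean expression in 20 bins, and it is said to lie outside the random range when it falls outside the middle 95% of these lists. That describes these libraries and is not a test of the conditions. With 26 lists per comparison, between 4 and 7 lay outside in each of the 7 comparisons.

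The rule for named genes was also set in advance. It takes Ptgs2, Ptgs1, Esr1, Esr2 and Gper1 in every library, the 12 largest differences each way among the 6699 rows in each main comparison (for hypoxia against control only genes on the same side of the control in all 4 hypoxic libraries), the 2 highest and 2 lowest detected members of each list, list members at least 2-fold different in the same direction with all 3 compounds, and the 5 largest differences each way between compounds. Symbols of uncharacterised loci and small RNAs were left out of the rankings, and further genes, mostly other members of the lists such as Acta2, Pgk1 and Ldha, were named after their values were seen. A few genes that the rule takes are not reported here. Of 16881 distinct symbols, 16490 were found in the RefSeq gene table of assembly GRCr8, which was used only for names and for which genes neighbour each other; 149 symbols stand on more than 1 row. Tnf and its neighbour Lta hold almost the same values (gap of at most 0.003) in every library, so reads may have been counted for both and Tnf is uncertain. Eno2, Tpi1 and the ribosomal RNA symbol Rn5-8s also stand on several rows. Transcript length and base composition were not analysed here.

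Genes set by hypoxia were followed in the compound libraries, once with the hypoxia library used to choose them and once with the other hypoxic libraries used instead, since a library that chooses genes and then serves as the reference pulls the difference toward control by chance. The alternatives were median centring, quantile normalization, pseudocounts of 0.1 and 5, no filter beyond detection, the 3350 most abundant rows, and thresholds of 1.5-fold and 3-fold. The scripts were tested on simulated libraries with a biological coefficient of variation of 0.1, which was assumed, since 1 library per condition cannot measure it. The simulation therefore checks the scripts and gives no error rate for the observed counts. For hypoxia against control, 6580 simulated genes were run; of 100 genes changed 4-fold and 100 changed 3-fold, 78 and 79 passed the abundance filter and 100% of these were called in the right direction, and 0 of 6423 unchanged genes were called. A simulated list of 20 genes raised 4-fold lay at percentile 100 and a list of 20 unchanged genes at 30.97. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.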

Results

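The data are 5 RNA-seq libraries of rat vascular smooth muscle cells: control, hypoxia, and hypoxia after In-Cl, DPN or E2. Each condition is 1 library, so the counting intervals below cover counting error only and nothing can be said of the spread between cultures. The intervals of medians describe the spread over genes within a pair of libraries. The deposited linear values sum to 20663687 in the control, 22837695 in hypoxia, 21763657 with In-Cl, 22185239 with DPN and 22090980 with E2. Differences are on the scale of log2(adjusted read count + 1), and counts of genes cover the 6699 most abundant rows.

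Hypoxia against control asks what low oxygen for 24 h does to these cells. Genes of sugar breakdown and of the response to low oxygen stood far above the control. Pygl, the liver form of glycogen phosphorylase, was 60.7-fold higher (log2 5.92, counting interval 5.52 to 6.41). Slc16a3, which exports lactate, was 33.1-fold higher and Egln3, a prolyl hydroxylase that marks hypoxia-inducible factor for degradation, 34.9-fold higher. Ndufa4l2, a mitochondrial protein induced by hypoxia, was listed at 0 in the control and reached 491 reads in hypoxia, at least 199-fold higher if the control is set at a floor of 3 reads; the counting interval, which takes in the error of both libraries, starts lower, at 161-fold. On the other side, the endoplasmic reticulum chaperone Calr was 2.10-fold lower (log2 -1.07, interval -1.10 to -1.05), and the cell death kinase Ripk3 was 2.48-fold lower.

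Also among the 12 largest differences upward were Ak4, a mitochondrial adenylate kinase (38.0-fold), Vwa1 (24.5-fold), Ndrg2 (20.6-fold), Ankrd37 (15.8-fold), the aldolase Aldoc (14.7-fold), Fam162a (14.3-fold), the enolase Eno2 (13.2-fold, on 2 nearly identical rows) and the mitophagy receptor Bnip3 (12.2-fold). The 12 largest differences downward were smaller. Ppil3, a peptidyl-prolyl isomerase, was 2.37-fold lower, and so by similar amounts were Naa10 (2.28-fold), the pyrophosphatase Ppa1 (2.27-fold), Tuba4a (2.26-fold) and the epoxide hydrolase Ephx1 (2.16-fold). The chaperone Hsph1 was 2.09-fold lower, the folate enzyme Shmt1 2.06-fold, the matrix proteoglycan Lum 2.05-fold and the complement regulator Cd55 2.04-fold.

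In the glycolysis list 18 of 22 detected genes were at least 2-fold higher and 0 were lower, with a median of 2.37. Pgk1 was higher by 3.26, Ldha by 2.94 and Gapdh by 1.92. Pfkfb4 was the lowest member at -0.47, with an interval from -0.97 to 0.01. In the hypoxia response list 19 of 27 detected genes were at least 2-fold higher, with a median of 2.53. The glucose transporter Slc2a1 was higher by 3.17 and the angiogenic factor Vegfa by 1.53, while Car12, a carbonic anhydrase, rested on 2 reads in the control (log2 6.19, interval 5.10 to 10.03). Endothelin, Edn1, was lower by -0.31 (interval -0.39 to -0.23), and Angptl4 had 9 reads in the control and 4 in hypoxia. Both medians lay above all 10000 random lists (percentile 100).

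A further 5 lists lay outside the random range. Of 33 cell cycle genes 28 were below 0, with a median of -0.24 (percentile 0.06): cyclin E, Ccne1, was at -1.01 and thymidylate synthase, Tyms, at -0.63, while Cenpf (0.18) and Mki67 (0.14) were above 0. Of 13 heat shock genes 10 were below 0, with a median of -0.26 (percentile 0.22) and Hspd1 at -0.62, and Hspa1b (0.44) went the other way. Ribosomal protein genes were above 0 in 73 of 78 cases, with a median of 0.21 that was 0.00 after quantile normalization. The histones, 23 of 27 above 0, had a median of 0.70 that was 0.46 with values under 3 reads raised to that level; Hist2h2ab was highest at 1.69, and 4 members were among the 6699 rows. The name pattern of this list also took H19, an imprinted noncoding RNA, and the replacement histones H3f3b and H1f0. The epithelial markers had a median of 1.18, or 0.78 with low values raised, and rested on Epcam with 24 reads against 8 and Cdh1 with 8 against 3.

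The other 19 lists with a percentile lay inside the random range, though with values under 3 reads raised the synthetic phenotype list lay outside it (median 0.31, percentile 99.6). Of its members, 2 were under that level in at least 1 of these libraries, so the fixed difference may enter this median. The contractile genes had a median of 0.12, with 11 of 22 above 0 and 4 below 0 by their counting intervals: Des was at 2.63 (31 reads against 5), Pln, the calcium pump regulator, at -2.02 and Smtn at -0.99. The extracellular matrix list had a median of 0.16, in which the collagen cross-linking enzyme Loxl2 (2.34) and the lysyl hydroxylase Plod1 (2.01) were highest. Mitochondrial respiration had a median of -0.135, with 23 of 30 genes below 0 and cytochrome c, Cycs, at -0.71, but the hypoxia isoforms Ndufa4l2 and Cox4i2 (4.44) stood apart above 0. Endoplasmic reticulum stress genes went both ways, with Trib3 at 1.64, Vldlr at 1.01 and Sdf2l1 at -1.18, around a median of -0.005. The oxidative stress list had a median of -0.10 with the metallothioneins Mt1a (2.22) and Mt2A (1.53) highest. Medians were 0.07 for inflammation, 0.08 for interferon (Ifih1 at -1.15), 0.21 for estrogen targets (Rara at 1.22), 0.25 for the synthetic phenotype (Klf5 at 1.03), -0.07 for cholesterol synthesis (Acat2 at -0.71), 0.21 for immediate early genes (Ier3 at 1.29, Egr1 at -0.98) and 0.00 for prostanoids. The estrogen receptor list, 4 detected genes, had a median of 0.80. Most markers of other cells lay outside the 6699 rows: medians were 0.23 for endothelium (Tek at 0.60, Flt1 at -1.17), -0.02 for leukocytes, 0.17 for fibroblasts (though Lum was at -1.04, with 572 reads against 1432), 0.47 for adipocytes, 0.17 for neural crest or glia and -0.88 for erythroid cells, whose 3 detected members had 0 to 2 reads in these 2 libraries.

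**Figure D1:**
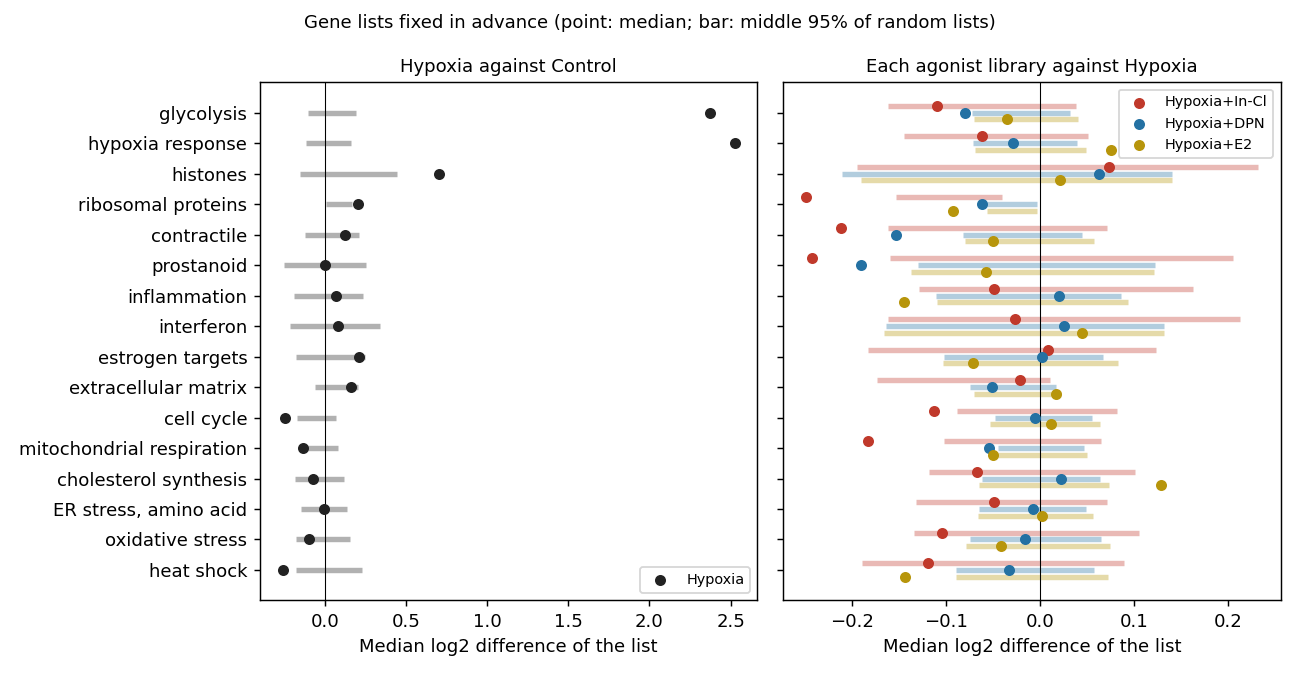
Median log2 difference of 16 gene lists, for hypoxia against control on the left and for each compound library against hypoxia on the right; each point is 1 list in 1 comparison, and the pale bars span the middle 95% of 10000 random lists matched on expression. Glycolysis (2.37) and hypoxia response (2.53) stand far to the right in hypoxia, while the lowest of these 16 medians in a compound library is -0.25, for ribosomal proteins with In-Cl.

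In all, 126 of the 6699 genes were at least 2-fold higher in hypoxia and 15 were at least 2-fold lower. The lower count was not stable: median centring gave 132 higher and 9 lower, quantile normalization 129 and 11, and the In-Cl library in place of hypoxia 152 and 36. Of the 126, 106 were at least 2-fold above the control in all 4 hypoxic libraries, and of the 15 only Ripk3, Ppa1, Tuba4a and Shmt1 were at least 2-fold below it in all 4. These 4 comparisons share the same control library, and the hypoxia library, 1 of the 4, also chose the genes. For 4851 genes (72.4%) the control lay outside the range of the 4 hypoxic libraries. The share would be 40% if all 5 libraries were interchangeable. The control is a single library, so the excess cannot be assigned to hypoxia. With no filter on abundance the count was 1186 higher and 435 lower, most of it among less abundant rows, and at 1.5-fold it was 294 and 227.

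COX-2, the enzyme that makes prostaglandin precursors and the gene in the series title, is Ptgs2. It was 2.32-fold higher in hypoxia than in the control (log2 1.21, counting interval 0.91 to 1.53), with 131 reads in the control and 250 in hypoxia. Its mean lay under the cut of 310.5 for the 6699 most abundant rows, so it is not counted among the 126. With In-Cl it had 221 reads and stood 1.18-fold below hypoxia (log2 -0.24, interval -0.51 to 0.02), and with DPN it had 209 reads and stood 1.16-fold below (log2 -0.22, interval -0.50 to 0.05). With E2 it had 279 reads and was 1.19-fold above hypoxia (log2 0.25, interval -0.01 to 0.50). All 3 intervals against hypoxia included 0, so a difference from hypoxia was not detectable at this depth. Ptgs2 in the In-Cl library was lower than in the E2 library (log2 -0.49, interval -0.75 to -0.23), and the same held for DPN against E2 (log2 -0.46, interval -0.73 to -0.20). Of the 200 genes nearest to Ptgs2 in mean level, 4 were as much higher in hypoxia.

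Other prostanoid genes followed their own courses. Ptges, the inducible prostaglandin E synthase, was 4.51-fold higher in hypoxia (log2 2.17, interval 1.68 to 2.76; 144 reads against 38) and stayed near that level with In-Cl (0.20 against hypoxia), DPN (0.23) and E2 (-0.09). Ptgs1, the constitutive COX-1, had 23 reads in the control, 18 in hypoxia, 48 with In-Cl, 27 with DPN and 38 with E2. It was higher than in hypoxia with In-Cl (log2 1.30, interval 0.54 to 2.22) and with E2 (log2 1.11, interval 0.32 to 2.06). Tbxa2r, the thromboxane receptor, was 0.80 higher in hypoxia and lower than hypoxia with In-Cl (-0.43), DPN (-0.27) and E2 (-0.28); it was named after its values were seen. The prostacyclin receptor Ptgir and Hpgd, the enzyme that degrades prostaglandins, differed at least 2-fold in the same direction with all 3 compounds, but on 0 to 4 reads. The receptors of the compounds themselves were close to the detection limit. Esr1 had 4 reads in the control, 9 in hypoxia, 16 with In-Cl, 3 with DPN and 12 with E2; Esr2 had 4, 14, 15, 22 and 6 in the same order. Gper1 had between 3 and 7 reads in every library. Esr2 was higher in hypoxia than in the control by its counting interval (0.42 to 4.15).

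**Figure D2:**
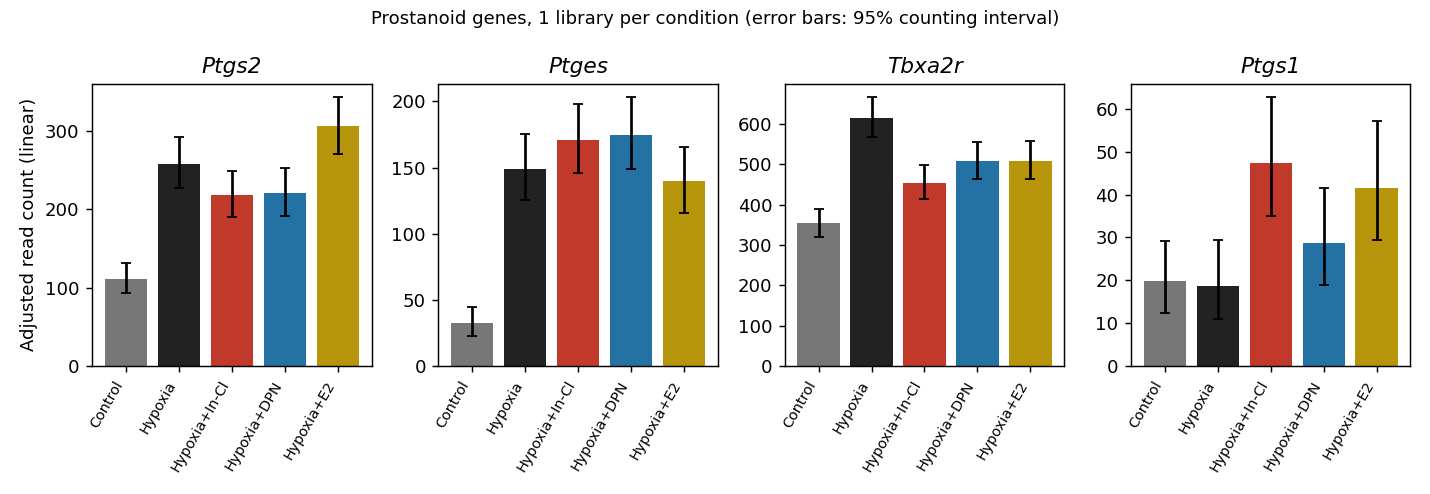
Adjusted read count on a linear scale for Ptgs2, Ptges, Tbxa2r and Ptgs1 in the 5 libraries; each bar is 1 library and the error bars are 95% Poisson counting intervals. Ptgs2 goes from 111 in the control to 258 in hypoxia, and the 3 compound libraries lie around the hypoxia value.

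In-Cl against hypoxia asks what the indazole compound adds to hypoxia. Few abundant genes differed by 2-fold, and 0 were lower by that much. Lnpep, an aminopeptidase of glucose transporter vesicles, was 2.32-fold higher (log2 1.21, interval 1.01 to 1.44) and the cell adhesion receptor Cxadr 2.09-fold higher. The actin gene Acta2 was lower by -0.49, with Cnn1, calponin, at -0.57 and Tagln at -0.39. Nearly every ribosomal protein gene was slightly lower, with a median of -0.25.

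Cxadr and Lnpep were followed by Phc3 (1.99-fold), the basement membrane protein Fras1 (1.93-fold), the nuclear receptor Nr2c2 (1.90-fold), Chm (1.88-fold), Plxna3 (1.80-fold), Sesn3 (1.75-fold), the cationic amino acid transporter Slc7a2 (1.74-fold), Myo9a and Kif13b (both 1.73-fold) and Crispld2 (1.71-fold). The other 2 of the 4 genes at least 2-fold higher were uncharacterised, LOC680227 (1.23) and LOC498592 (1.09). The lowest genes were Rasl2-9 (1.97-fold lower), the RNA polymerase subunit Polr2i and the carbonyl reductase Cbr1 (both 1.83-fold), Lgals9 (1.70-fold), the urea cycle enzyme Asl (1.67-fold), Svbp (1.60-fold), Mfap5 (1.59-fold), the cold-inducible RNA-binding protein Rbm3 (1.55-fold), Cgref1 (1.52-fold) and Ino80b, Lce1m and Exosc5 (each 1.51-fold). At 1.5-fold, 82 genes were higher and 13 lower.

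Of the contractile genes 12 of 22 lay below 0 by their counting intervals and 3 above, with a median of -0.21 (percentile 0.26). Actg2 was lowest at -1.09, and Myl9 (-0.47) and Tpm2 (-0.45) were also lower, while Mylk (0.39), Cald1 (0.12) and Vcl (0.03) were not. Ribosomal protein genes lay below 0 by their intervals in 75 of 78 cases, below all random lists, with Rps28 at -0.39. Mitochondrial respiration had a median of -0.18 (percentile 0.02), with 19 of 30 genes below 0 by their intervals and Cox4i2 at -0.44. The cell cycle list had a median of -0.11 (percentile 0.57), with thymidine kinase, Tk1, at -0.35 and Plk1 at -0.34 but Cenpf at 0.30 and Kif11 at 0.29. The prostanoid list had a median of -0.24 (percentile 0.295), which became -0.10 and lay inside the random range (percentile 2.57) with values under 3 reads raised to that level. The fibroblast markers, at -0.30 (percentile 1.46), became -0.07 by the same step and lay inside the random range (percentile 12.2). Glycolysis (-0.11), hypoxia response (-0.06) and estrogen targets (0.01) lay inside the random range; the chemokine Cxcl12 was the highest estrogen target at 0.48, and Egr1, an immediate early transcription factor, was 2.21-fold higher (198 reads against 85).

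DPN against hypoxia asks the same of the diarylpropionitrile. Apart from a run of 7 genes that are neighbours in file order, which were far lower in the DPN library alone, few abundant genes differed. Chm, an escort protein for lipid modification of Rab proteins, was 1.80-fold higher (log2 0.85, interval 0.62 to 1.09), and Omd, a matrix proteoglycan, 1.72-fold higher. The contractile genes were lower with a median of -0.15 (percentile 0.01), with Acta2 at -0.40 and Cnn1 at -0.36.

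The 7 neighbours, in file order, were St5 (-3.31), Akip1 (-2.14), LOC499240 (-7.23), Ascl3 (-7.95), Tmem9b (-3.93), Nrip3 (-6.32) and Dennd5a (-3.32). The gene table has 6 of them in this order on chromosome 1, St5 under the name Dennd2b, with 1 protein-coding gene between Akip1 and Ascl3 and 1 between Nrip3 and Dennd5a, and LOC499240 was not found in it. The genes on either side, Rpl27a (-0.24) and Tmem41b (0.04), did not share the difference. Those 7 and RGD1305298 (-1.25) made up the 8 genes at least 2-fold lower with DPN, and 0 were higher; without the 7 and the ribosomal RNA rows, an exclusion chosen after the data were seen, the count was 1. The next highest genes were Fam122b (1.61-fold), the phosphatase Dusp22 (1.58-fold), the complement gene C4a (1.55-fold), Crispld2, Setd7, Plxna3, Ppil3, Nr2c2, Mob1b and Sesn3 (log2 0.49 to 0.59). Beside the run, the lowest were the myosin Myh1 (1.65-fold lower), the small heat shock protein Hspb6 (1.61-fold), Cadm4 (1.55-fold), Lsm2 (1.52-fold), Rbm3 (1.48-fold) and Rasgrp4 (1.45-fold).

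**Figure D3:**
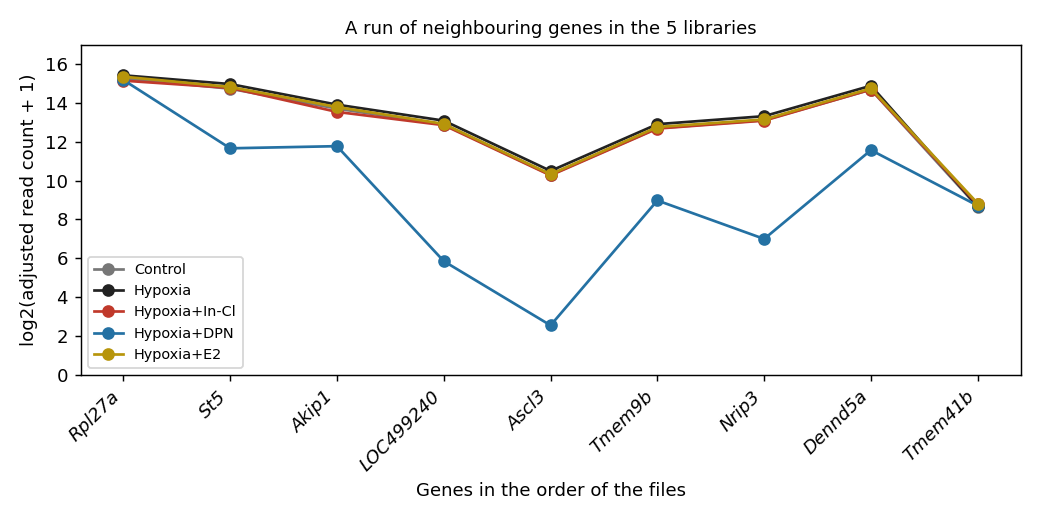
Deposited log2 values, log2(adjusted read count + 1), of 9 neighbouring genes in file order, with 1 line per library. From St5 to Dennd5a the DPN line lies below the other 4, by a log2 difference of -7.95 at Ascl3 against hypoxia, and at Rpl27a and Tmem41b the 5 lines meet.

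Of the contractile genes 12 of 22 lay below 0 by their intervals with DPN and 2 above; Pln was above at 0.47. The glycolysis list had a median of -0.08 (percentile 1.14), with 20 of 22 genes below 0 and Gapdh at -0.22, and -0.04 after quantile normalization. The prostanoid median was -0.19 (percentile 0.515). Ribosomal protein genes had a median of -0.06 (percentile 2.35), which was -0.01 after quantile normalization. Mitochondrial respiration was at -0.0545 (percentile 0.91), or at -0.04 and inside the random range with low values raised. Hypoxia response (-0.03), estrogen targets (0.00), inflammation (0.02) and cell cycle (-0.005) lay inside the random range. Egr1 had 167 reads against 85 in hypoxia, a counting interval that starts at 0.62, and Dcn, a matrix proteoglycan, had 14 reads in hypoxia and 0 with DPN.

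E2 against hypoxia asks the same of the natural hormone, given at 10 nM rather than 0.1 µM. Genes of cholesterol synthesis stood slightly higher, with a median of 0.13 (percentile 99.98). Acat2 was at 0.24, while Dhcr7 was at -0.27. Heat shock genes were slightly lower, with a median of -0.14 (percentile 0.03) and Hspa1b at -0.28. Cbr1, a carbonyl reductase, was 1.98-fold lower (log2 -0.99, interval -1.05 to -0.92), as it was with In-Cl.

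Of the abundant genes 0 were at least 2-fold higher and 2 were lower, namely a row of the ribosomal RNA Rn5-8s (-5.48) and LOC310926 (-2.07), both named after their values were seen. Lnpep (1.87-fold), Dusp22 (1.70-fold) and Cxadr (1.61-fold) were highest, followed by the calcium channel subunit Cacna2d1 (1.52-fold), Nr2c2 (1.51-fold), and the copper transporter Atp7a, Crispld2, Abcg3, Slc39a9, Gpt2, Fam122b and the collagen Col8a1 (log2 0.54 to 0.59). After Cbr1, the lowest were Asl (1.66-fold), Rasl2-9 (1.65-fold), Ino80b (1.57-fold), Lce1m (1.48-fold), the Wnt inhibitor Dkk1 (1.45-fold), the bile acid transporter Slc10a2 (1.43-fold), Fam160b2, Scand1 and Evpl (each log2 -0.49) and the ribosomal RNA rows Rn28s (1.42-fold) and Rn18s (1.41-fold).

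The hypoxia response list was slightly higher with E2, with a median of 0.08 (percentile 99.7), Ak4 at 0.31 and the endoplasmic reticulum oxidase Ero1a at 0.29. Of its 27 genes, 10 lay above 0 by their counting intervals and 6 below, with Mxi1 lowest at -0.165. Ribosomal protein genes had a median of -0.09, below all random lists, and 70 of 78 lay below 0 by their intervals. Mitochondrial respiration had a median of -0.05 (percentile 2.46) and lay inside the random range with low values raised (percentile 3.42). The inflammation list had a median of -0.145 (percentile 0.79) on members with few reads. With values under 3 reads raised to that level it lay inside the random range (percentile 71.1). Its median was then 0.07, the fixed difference of a gene under that level in both libraries, so this sign says nothing of the genes. Estrogen targets (-0.07), contractile genes (-0.05), glycolysis (-0.035) and prostanoids (-0.06) lay inside the random range; among prostanoid genes the receptor Ptgfr was 4.57-fold higher on 29 reads against 6.

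Whether a compound moved the cells back toward the control was read from the genes set by hypoxia. Among the 126 genes that were higher in hypoxia, the median against hypoxia was -0.06 with In-Cl (interval of the median -0.11 to -0.01), -0.05 with DPN (-0.08 to -0.03) and -0.001 with E2. The median of the same 126 genes in hypoxia against the control was 1.69, and that of the 15 lower genes -1.07. When the genes were chosen without the hypoxia library, the medians were -0.04 over 125 genes, -0.03 over 137 and 0.04 over 128. Their intervals were -0.08 to 0.03 with In-Cl, -0.051 to -0.001 with DPN, toward the control, and 0.01 to 0.08 with E2, away from it. Among the 15 genes that were lower in hypoxia the medians were -0.03 with In-Cl, 0.16 with DPN (0.01 to 0.30) and 0.07 with E2; chosen without the hypoxia library they were -0.20 over 24 genes, -0.03 over 27 and -0.09 over 27. The intervals of these last medians were -0.26 to -0.15 with In-Cl and -0.16 to -0.01 with E2, away from the control, and -0.13 to 0.01 with DPN, which includes 0. Genes chosen without the hypoxia library were picked by the other compound libraries. Anything these share with the measured library favours a difference away from the control, so such medians do not show movement away from it. All intervals of medians here are over genes, which are not independent replicates, so they do not measure the spread between cultures. In simulated libraries with no compound effect and a threshold of 1.5-fold, genes lower in hypoxia had medians of 0.10 (In-Cl), 0.12 (DPN) and 0.10 (E2) when the hypoxia library chose them and -0.004, 0.05 and 0.03 when it did not. The simulated genes higher in hypoxia had medians of 0.02, -0.03 and -0.01 with it and 0.06, 0.00 and 0.03 without it. These simulated sets came from a single draw, held genes planted at 3-fold and 4-fold, and used a lower threshold than the observed sets. They therefore do not give the size of the bias in the observed genes. LOC498592, which stands on 2 rows, had the only row among the 6699 that was at least 1.5-fold different in the same direction with all 3 compounds.

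The differences of the compounds from hypoxia share the hypoxia library and so correlate by chance. Across the 6699 genes, which are not independent replicates, r was 0.40 for In-Cl and DPN, 0.56 for In-Cl and E2 and 0.36 for DPN and E2. Libraries simulated with counting error only gave 0.50, 0.50 and 0.49. The 7 neighbouring genes, far lower in the DPN library alone, were among these genes and widened the DPN differences. The value of r was not computed without them, so the values with DPN cannot be read against the simulated ones. The covariances were 0.0193, 0.0200 and 0.0130, against a simulated 0.0027, 0.0026 and 0.0027. No control library can be split here, and the simulation leaves out variation between cultures, so part or all of the excess may come from the shared hypoxia library.

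In-Cl and DPN, both at 0.1 µM, were compared directly. Apart from the 7 neighbouring genes, the In-Cl library was at least 2-fold higher for RGD1305298 (1.23) and LOC680227 (1.02) and lower for LOC102723236 (-1.20), of 10 such genes in all. Asl (1.66-fold), C4a (1.65-fold), Polr2i and Snrpa1 (both 1.49-fold) and Rasl2-9 (1.46-fold) were lowest with In-Cl. Ribosomal protein genes were lower with In-Cl by a median of -0.19, mitochondrial respiration by -0.10 (percentile 0.835) and endoplasmic reticulum stress genes by -0.11 (percentile 2.12), while the extracellular matrix list lay higher at 0.03 (percentile 99.4). The contractile and prostanoid lists of these 2 libraries did not lie outside the random range, and Ptgs2 differed by -0.02 (interval -0.30 to 0.26).

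E2 was given at 10 nM, so its comparisons with the other 2 compounds also differ in dose. Against E2 the contractile genes were lower with In-Cl (median -0.23, below all random lists) and with DPN (median -0.16, percentile 0.01), and Cnn1 was 1.56-fold lower with In-Cl. Cholesterol synthesis genes were lower than with E2 in both, by -0.17 with In-Cl and -0.08 with DPN (percentile 0.41). Ribosomal protein genes were lower with In-Cl (-0.15) and higher with DPN (0.03, percentile 99.9). Respiration genes were at -0.09 with In-Cl (percentile 1.45) and extracellular matrix genes at 0.04 (percentile 99.8), and the prostanoid median was -0.14, inside the random range (percentile 12.03) with low values raised. With DPN against E2 the heat shock genes were at 0.07 (percentile 98.2), immediate early genes at 0.09 (percentile 97.6) and glycolysis at -0.06 (percentile 2.04).

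Among single genes, Ccp110 (1.86-fold), the matrix proteoglycan Fmod (1.80-fold), Fras1 (1.68-fold), Ccnl2 and Plxna3 (both 1.60-fold) were highest with In-Cl against E2. Rbm3 (1.71-fold), Lgals9 (1.69-fold), Polr2i (1.56-fold) and Fkbp11 (1.53-fold) were lowest beside Cnn1. With DPN against E2, C4a (2.10-fold), Evpl (1.73-fold), Asl (1.66-fold), Fmod (1.58-fold) and Cgnl1 (log2 0.59) were highest, and the 7 neighbouring genes were lowest. The counts at 2-fold were 3 genes for In-Cl against E2 and 11 for DPN against E2, and 2 and 3 without the 7 neighbours and the ribosomal RNA rows.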

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

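The alternatives without the 7 neighbouring genes and the ribosomal RNA rows, with another hypoxic library in place of hypoxia, and with values under 3 reads raised to that level were chosen after seeing the data. Median centring, quantile normalization and pseudocounts of 0.1 and 5 kept all 7 total counts of genes within 1.5 times, but of the hypoxia count the lower part of 15 was 9 with median centring and 11 with quantile normalization. They moved the Ptgs2 differences by less than their counting intervals. Counts depended on the abundance filter and the threshold, as these settings add or remove genes by construction. With no filter beyond detection the counts were 1621 (hypoxia against control, main count 141), 1116 (In-Cl against hypoxia, 4), 1289 (DPN, 8), 1225 (E2, 2), 1080 (In-Cl against DPN, 10), 1024 (In-Cl against E2, 3) and 1311 (DPN against E2, 11). At 1.5-fold they were 521, 95, 20, 15, 37, 24 and 17 in that order. At 3-fold the count was 67 for hypoxia against control and 0 for In-Cl against hypoxia, and among the 3350 most abundant rows 83 and 0. With In-Cl, DPN or E2 in place of hypoxia the count against the control was 188, 140 and 147, of which 36, 18 and 21 were lower (15 with hypoxia). Without the 7 neighbours and ribosomal RNA rows it was 1 for DPN, 1 for E2, 3 for In-Cl against DPN and 3 for DPN against E2.

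Choosing genes without the hypoxia library gave returns of -0.20 (In-Cl, genes lower in hypoxia), -0.03 (DPN, higher), -0.03 (DPN, lower, from 0.16), 0.04 (E2, higher) and -0.09 (E2, lower). The part of the hypoxia library as both chooser and reference is removed by construction, but what the compound libraries share may then push the median away from the control. At 3-fold there were 0 genes lower in hypoxia to follow. Of the gene lists, raising values under 3 reads turned inflammation with E2 to 0.07. That value is the fixed difference of genes under that level in both libraries, so the turn is made by the step itself. Quantile normalization took the ribosomal protein median in hypoxia to 0.00. Among list medians and their alternatives, run for the 4 comparisons with the control or hypoxia only, 588 stayed inside the interval of the median and 19 left it without turning a list that lay outside the random range; of the named gene differences 606 stayed inside their counting interval and 10 left it, with 0 turned. Raising values under 3 reads also put lists outside the random range: synthetic phenotype in hypoxia (percentile 99.6), endothelial markers with E2 (1.23), neural crest or glia with In-Cl against hypoxia (98.7) and against DPN (98.6), and synthetic phenotype with DPN against E2 (2.39). Fixed differences of genes under that level can enter these medians, though the random lists were raised in the same way. Few reads limit Ptgs2, Ptgs1 and the estrogen receptors, at 3 to 279 reads.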

Other observations

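All tests below were chosen after the results they bear on were seen. Beyond the comparisons, the smooth muscle libraries held a few abundant rows whose share differed between libraries. The ribosomal RNA row Rn45s took 2.26% of the control, 2.68% of hypoxia, 2.14% of In-Cl, 2.78% of DPN and 2.11% of E2, next to elastin, Eln, at 2.46%, 2.38%, 2.41%, 2.27% and 2.17%. Outside the 6699 most abundant rows, the pheromone receptor genes Vom2r2 and Vom2r3 were higher in hypoxia than in the control, by 4.56 and 3.76. They were lower in the E2 library than in hypoxia, by -1.53 and -1.46, and no counting interval is given for either. Il6 was at 6.97 in the control, 7.42 in hypoxia, 7.04 with In-Cl, 7.62 with DPN and 7.58 with E2.

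The first pattern is the run from St5 to Dennd5a in the DPN library. If 1 source of reads reached all 7 genes in the other 4 libraries, the 7 genes would keep the same ratio among these 4. The SD over the 7 genes of the log2 difference from the control was 0.0340, averaged over the other 3 hypoxic libraries. On the excess over the DPN library it was 0.0499. There Akip1 departed from a common ratio with In-Cl, at -0.23, while the other genes lay between -0.03 and 0.05. The SD of whole levels had a median of 0.317 and a lowest value of 0.0832 among 6686 runs of 7 neighbouring rows. Its lowest value was 0.0820 among 10000 sets of 7 rows at the same levels, which argues against separate regulation of each gene. Reads shared between these neighbours may therefore account for the pattern, but a common ratio does not tell this from regulation in common. The excess over the DPN library in the control ran from 1250 at Ascl3 to 23951 at St5. The same reads were thus not counted in full for every gene. Why the DPN library lacks such reads is not known, and an effect of DPN on 1 common transcript stays open.

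The second pattern is the lower level of contractile genes with In-Cl. Counting error alone is argued against, since 12 of 22 members had counting intervals below 0. The ribosomal protein genes, which have short transcripts, were lower by a median of -0.249 in the same library. This check used no transcript lengths, so it cannot tell a smaller yield of reads from short transcripts from other causes of that fall. Such a smaller yield stays open as a part of the contractile difference. Both lists were also below 0 in the other compound libraries, in other proportions: with DPN the contractile median was -0.15 and the ribosomal protein median -0.06, and with E2 they were -0.05 and -0.09. These differences share the hypoxia library, whose medians against the control were 0.12 for contractile and 0.21 for ribosomal protein genes. Falls in common may therefore come in part from that library. Against E2, without the hypoxia library, the contractile median was -0.23 with In-Cl and -0.16 with DPN. These values argue against the hypoxia library alone for the contractile falls in those libraries. The ribosomal protein median against E2 was -0.15 with In-Cl, which argues the same way, but 0.03 with DPN, which does not. These comparisons rest on the single E2 library. An effect of In-Cl on the contractile state stays open and was not tested, as there is 1 culture per condition and transcript lengths were not analysed here.

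The third pattern is Ptgs2 below its hypoxia level with In-Cl and DPN. The counting interval of the In-Cl difference reached up to 0.0233 and that of DPN to 0.0476, so both include 0 and counting error may account for either. Of the 200 genes nearest in mean level, 18.5% were at least as much lower in the In-Cl library, and 14% in the DPN library, so the Ptgs2 difference lies within the spread of genes at its level. An effect of the compounds on Ptgs2, the subject of the series title, stays open and needs replicate cultures.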
